A study of Homo sapiens with 2 samples.

How the data were processed

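Gene expression was measured on Affymetrix microarrays in total RNA from 2 human cell lines labelled as breast cancer, with 1 array for each line. MCF7 is an established oestrogen receptor-positive breast carcinoma line, and the labels call it doxorubicin sensitive. MCF7_ADR is labelled doxorubicin resistant and, per the labels' protocols, was developed from MCF7 under rising doses of doxorubicin that reached 1 mM. Both lines were grown in the same medium. The samples were grouped by these labels.

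The deposited table holds 1 value per probe set and array on the log2 scale, as judged from the values, since no header or label names the scale. The background correction, normalization and summarisation that the authors used are not given in the sources used here. The sorted deposited values of the arrays lie within 0.185 of each other, so their distributions were close to equal before deposit. Such processing removes any change in total RNA per cell, and a fold below is relative to the other genes on the array. The deposited table has 51408 probe sets per array, with medians of 5.12 in MCF7 and 5.09 in MCF7_ADR. The file carries no detection calls, and the number of arrays limits the precision.

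Probe sets were named from the platform annotation, which gives 1 gene symbol to 16098 of them, several symbols to 0 and no entry to 35310. All 16098 gene identifiers of named probe sets matched the RefSeq gene table of assembly GRCh38.p14, which was used for current symbols and for the order of neighbouring genes only. No coordinates are given because the genome build of the array design is not given in the sources used here. Older symbols in the gene lists were updated through the same table. XIST and Y-linked genes (12 probe sets) were left out, and the remaining named probe sets stood for 14873 genes. A gene with several probe sets (778 genes) was represented by the one with the highest mean of both arrays.

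A floor was set on each array at its 50th percentile over all probe sets, control probe sets included, since the numeric names do not mark them. Values below it were raised to it, and a gene below it on both arrays was not compared. This left 11311 genes, of which 10108 lay at or above the floor on both arrays. For a gene below the floor on 1 array, the fold is a lower limit and is written as at least that size. Differences are MCF7_ADR minus MCF7.

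With 1 array per line there is no spread between replicates, and no p-value, standard error or statistical test is given for any gene. Differences were instead sorted by size, at 2-fold, 4-fold and 8-fold. The only repeated measurement is that of several probe sets for 1 gene. Among 471 genes with 2 or more compared probe sets, all probe sets differed in the same direction for 349 (74.1%, 95% Wilson interval over genes 70.0 to 77.8). The pooled standard deviation of differences between probe sets of a gene was 0.49 on the log2 scale. It measures probe set and transcript form, not the spread between cultures.

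Before the data were examined, 40 gene lists were fixed. The median difference of a list with at least 5 compared members was placed among the medians of 10000 random lists of the same size, drawn from the same 10 bins of mean expression. A list at or above percentile 97.5, or at or below percentile 2.5, is said to stand outside the matched random range. This describes these arrays and is not a test of the cell lines. Of 35 lists that could be placed, 1.75 would stand outside by chance. Lists share some members and are not independent.

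The rule for named genes was also fixed in advance, among genes whose compared probe sets all differ the same way. It takes the 10 highest and 10 lowest differences among genes above the floor on both arrays, and the 6 brightest genes in each direction that lie below the floor on the other array. It adds up to 4 members of each list with the largest differences, and 20 genes chosen for their bearing on drug resistance or breast cell identity. Of those 20, 8 have no named probe set, so ABCB1, ABCG2, ABCC1, TP53, CDH1, ERBB2, CASP3 and CAV1 are not analysed here.

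The alternatives were a shift of each array to a common median, quantile normalization, the mean of a gene's probe sets, floors at the 30th and 70th percentiles and no floor. An alternative added after the data were seen kept only list members above the floor on both arrays. The scripts were tested on simulated data made from the real means of this comparison, with noise of 0.25 on the log2 scale and 200 of 11097 compared genes changed. Of genes changed by 2 log2 units 100% passed the 2-fold size, against 96% of those changed by 1.5 units and 0.34% of unchanged genes. The noise was a chosen setting, and neither the 0.49 between probe sets of a gene nor the spread between cultures was simulated. The 0.34% is therefore not an error rate for these arrays. Of 200 lists of unchanged genes drawn at random, 4% stood outside the matched random range. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.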

Results

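Genome-wide expression was compared between MCF7 cells and MCF7_ADR cells, labelled as a line kept under doxorubicin until it resisted the drug. Doxorubicin is an anthracycline that traps topoisomerase II on DNA. The comparison asks which genes differ between the drug-sensitive and the drug-resistant line. Each line was measured on 1 array of 51408 probe sets, so no value below has a replicate error. The arrays correlated across all probe sets with a Pearson r of 0.934, and across the 11311 compared genes with an r of 0.83. These correlations are across genes, which are not independent replicates. The median difference over compared genes was -0.04 on the log2 scale.

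The largest differences included members of the mesenchymal list on the higher side in MCF7_ADR, and of the luminal and epithelial junction lists on the lower side. The highest difference among genes above the floor on both arrays was that of AXL, a receptor tyrosine kinase (probe set 16862439), at 12.20 against 5.77 in MCF7, or 86.5-fold. MSN, which encodes the membrane-actin linker moesin (probe set 17104259), followed at 71.1-fold. FOSL1, a subunit of the AP-1 transcription factor, was 47.4-fold higher and the membrane protein gene EMP3 45.4-fold higher. SNAI2, a transcription factor of epithelial-mesenchymal transition, was 41.1-fold higher. The aminopeptidase gene ANPEP (40.4-fold), the matricellular gene CCN2 (36.7-fold), HEG1 (33.8-fold), FHL2 (32.0-fold) and the fibronectin gene FN1 (31.6-fold) completed the 10 highest. Most of these 10 are dim in MCF7, and their folds depend on where the floor is set. The brightest gene below the floor in MCF7 was MMP1, the interstitial collagenase (probe set 16743721), at 12.34 in MCF7_ADR and at least 149.3-fold higher. ANXA1, encoding annexin A1, was at least 61.3-fold higher and the growth factor gene FGF2 at least 42.1-fold. KRTAP2-3 (at least 64.4-fold), LINC02582 (at least 49.0-fold) and MT1L (at least 30.7-fold) were the others. KRTAP2-3 and MT1L belong to families of near-identical genes, so their signal cannot be assigned to 1 copy with certainty.

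In the other direction, SPDEF, an ETS factor of luminal cells (probe set 17018408), was at 11.93 in MCF7 and 6.27 in MCF7_ADR, 50.6-fold lower. GRHL2, which maintains epithelial identity, was 44.2-fold lower, and the heparan sulphatase gene SULF2 43.3-fold lower. The tight junction gene CLDN7 was 42.7-fold lower and the oestrogen-induced genes GREB1 and TFF1 were 36.8-fold and 24.0-fold lower. HID1 (31.9-fold), LINC00052 (28.1-fold) and TMEM150C (24.5-fold) were also among the 10 lowest. The non-coding RNA SNAR-B1 had the lowest difference among genes above the floor on both arrays, at 62.4-fold lower, and SNAR-D was at least 26.1-fold lower. The SNAR genes are near-identical copies and cannot be told apart on an array. DSCAM-AS1, a non-coding RNA of luminal breast cancer cells, lay below the floor in MCF7_ADR and was at least 92.5-fold lower. ANXA9 (at least 35.7-fold), TARP (at least 29.3-fold) and FOXA1 (at least 21.9-fold) were below the floor there as well. So was NF2, encoding the tumour suppressor merlin, at 9.62 in MCF7 and 4.52 in MCF7_ADR (at least 23.2-fold).

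**Figure D1:**
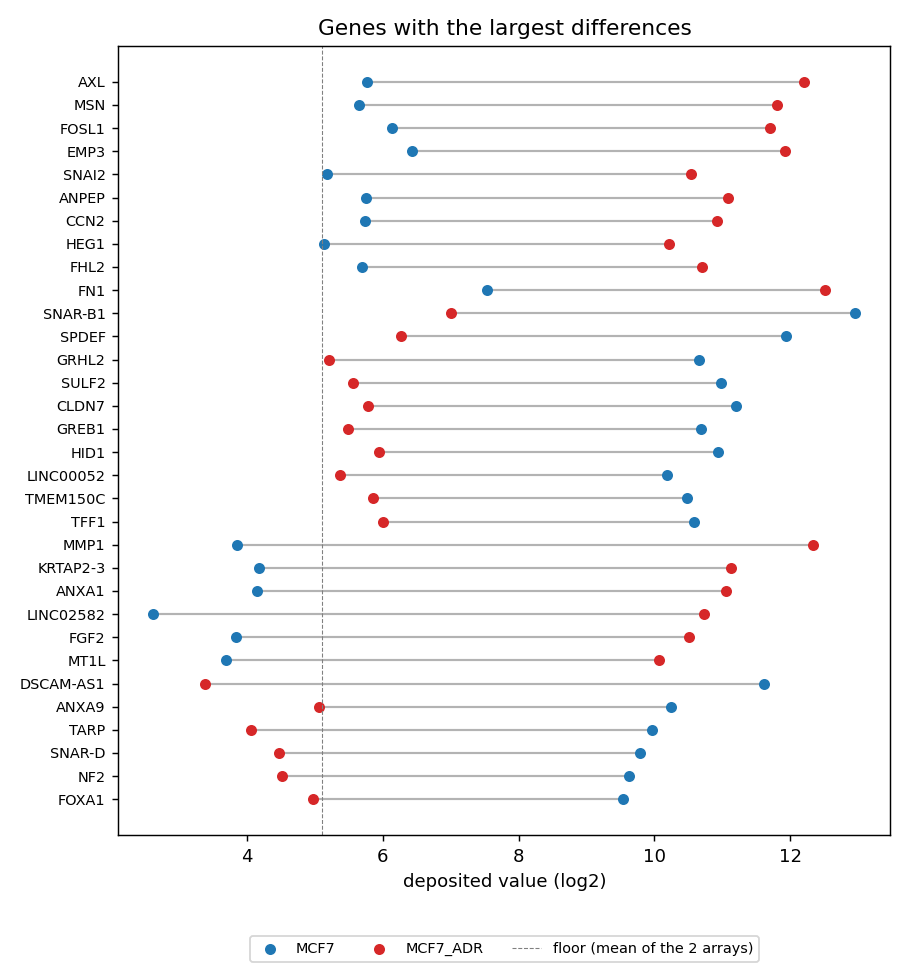
Deposited log2 values of the 32 genes named by size on the MCF7 array (blue) and the MCF7_ADR array (red), 1 array each; the dashed line is the mean of the floors of both arrays. AXL lies at 5.77 in MCF7 and 12.20 in MCF7_ADR, and DSCAM-AS1 at 11.62 and 3.38.

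Of the 11311 compared genes, 1037 (9.17%) were at least 2-fold higher in MCF7_ADR and 1018 (9.0%) at least 2-fold lower. At the 4-fold size the numbers were 305 and 228, and at the 8-fold size 114 and 94. Among the genes at the 2-fold size, 218 of the higher and 129 of the lower ones were limits set by the floor. Other probe sets of the same gene went the opposite way for 7 of the higher and 2 of the lower genes. Most genes had no second probe set to compare, as only 471 had 2 or more. Among the 97 of these with any probe set at least 2-fold apart between the arrays, all probe sets agreed in direction for 84 (86.6%). Under a floor at the 70th percentile the number of genes at least 4-fold higher was 192. The difference between the lines could not be separated from the spread between cultures, which was not measured.

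Luminal breast identity genes were lower in MCF7_ADR. Of 19 compared members, 14 were at least 2-fold lower, 0 were at least 2-fold higher, and the list median was -3.21 on the log2 scale, below every one of the matched random lists. ESR1, the oestrogen receptor (probe set 17013809), was at 9.24 in MCF7 and 4.84 in MCF7_ADR, at least 17.8-fold lower. GATA3, a master factor of luminal cells, was 20.5-fold lower, at 12.31 against 7.95. The luminal keratin gene KRT19 was 21.6-fold lower. The other keratin genes of the list moved less, with KRT8 at -0.81 and KRT18 at -0.50, and KRT18 stayed bright in MCF7_ADR (12.60). With the mean of a gene's probe sets in place of the brightest, the list median was -2.37.

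Oestrogen receptor targets were also lower, with 14 of 24 members at least 2-fold lower and 3 at least 2-fold higher. Their median was -1.23, against a matched random range of -0.36 to 0.27. GREB1 and TFF1 led the lower members, and FHL2, a LIM-domain cofactor, was the highest of the 3 that went the other way. Epithelial junction genes had a median of -1.82, with 20 of 30 members at least 2-fold lower and 1 at least 2-fold higher (random range -0.33 to 0.25). Besides CLDN7, the epithelial splicing regulators ESRP1 and ESRP2 were 18.5-fold and 16.1-fold lower, and the tricellular junction gene MARVELD2 was 17.3-fold lower. CD24, a surface marker of luminal cells, differed by 0.29, less than the 0.49 between probe sets of a gene.

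Mesenchymal genes were higher in MCF7_ADR. Of 22 compared members, 18 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 1.94 (random range -0.35 to 0.28). AXL, MSN, EMP3 and SNAI2 were the highest of them. VIM, the mesenchymal intermediate filament vimentin, was at 6.14 in MCF7 and 10.63 in MCF7_ADR, 22.4-fold higher. Of 23 listed basal and myoepithelial markers only 7 were compared. Their median was 0.91, and 3 of them were at least 2-fold higher. These were EGFR (22.4-fold), the oxytocin receptor gene OXTR (6.47-fold) and the keratin gene KRT7 (4.08-fold), and MME had a limit of 1.88-fold. The remaining members, KRT16 (0.34), KRT5 (0.18) and SFRP1 (0.06), differed by less than the 0.49 between probe sets of a gene. With a floor at the 30th percentile the basal list lay at percentile 95.1 of its random lists, inside the range. Annexin, S100 and linker genes went both ways, with 7 of 22 at least 2-fold higher and 5 at least 2-fold lower around a median of 0.47 (random range -0.35 to 0.28). MSN and ANXA1 were at one end. ANXA9 and S100A14 (9.48 in MCF7 and 4.68 in MCF7_ADR) were at the other.

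Growth factor receptor genes, mostly receptor tyrosine kinases, stayed as a list inside the random range (median -0.22), with 5 of 21 at least 2-fold higher and 6 at least 2-fold lower. The sign of that median is not settled, since it was 0.22 with the mean of a gene's probe sets and over members above the floor on both arrays. AXL, EGFR (5.81 against 10.30) and EPHA2 (9.46-fold) were higher, and ERBB4 was at least 9.46-fold lower. Integrins and matrix receptors had a median of 0.34 over 6 members, with the syndecan gene SDC2 6.46-fold higher and the collagen receptor gene DDR1 8.22-fold lower. Stem-like breast markers had a median of -0.01 over 8 members. Among them the hyaluronan receptor CD44 was 5.23-fold higher and the transcription factor SOX9 5.93-fold higher. SOX2 differed by -0.56 and NOTCH1 by 0.44.

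**Figure D2:**
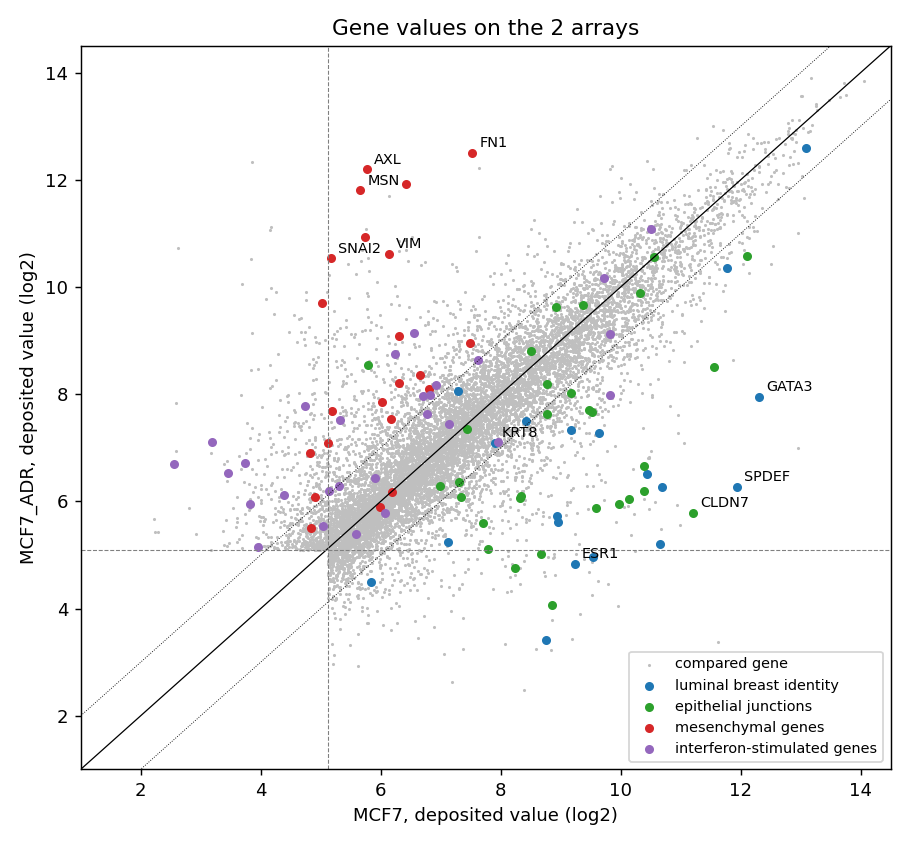
Deposited log2 value of each compared gene on the MCF7 array (x axis) and the MCF7_ADR array (y axis), with 4 gene lists in colour; the solid line marks equal values, the dotted lines a 2-fold difference and the dashed lines the floors. Luminal and epithelial junction genes lie mostly below the diagonal (14 of 19 and 20 of 30 at least 2-fold lower) and mesenchymal genes above it (18 of 22 at least 2-fold higher).

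Among genes tied to anthracycline handling, the annotation used here names only MVP of the ABC transporter list. MVP, the major vault protein, was 2.67-fold higher in MCF7_ADR. The topoisomerases were all within 2-fold over 7 members (median -0.62, random range -0.71 to 0.58). TOP2A, the replication-linked target of doxorubicin, differed by -0.86 and TOP2B by -0.62. TDP1 differed by -0.89 and TOP1 by -0.84. Carbonyl reductases and conjugating enzymes had 3 of 14 members at least 2-fold higher and 3 at least 2-fold lower (median -0.25). GSTP1, a glutathione transferase, was at 6.45 in MCF7 and 10.48 in MCF7_ADR, 16.4-fold higher. The ceramide galactosyltransferase gene UGT8, a lipid enzyme on that list, was 6.81-fold higher and GSTT2 at least 3.17-fold, while GSTM4 was 3.11-fold lower. GSTT2 and GSTM4 have close paralogs that probes can share.

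NRF2 antioxidant targets stayed near 0 (median 0.11), with 12 of 13 within 2-fold and GSR, glutathione reductase, 2.21-fold lower. OSGIN1 differed by -0.86, PGD by -0.63 and HMOX1 by -0.56. Of 11 superoxide and peroxide enzymes, 3 were at least 2-fold higher, namely GPX1 (5.07-fold), GPX8 (2.52-fold) and GPX3 (2.32-fold), and PRDX2 was 2.33-fold lower (list median -0.16). Glycosphingolipid enzymes had 4 of 11 members at least 2-fold higher and 0 at least 2-fold lower, but a median of 0.00 (random range -0.55 to 0.46). The glucosylceramide synthase gene UGCG was 3.13-fold higher, SPHK1 2.57-fold, SGMS2 2.28-fold and SGMS1 2.27-fold. Lysosome and autophagy genes had a median of 0.17, with CTSZ 9.45-fold, GABARAPL1 4.66-fold and CTSB 2.46-fold higher among 17 members.

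The anti-apoptotic list had a median of -0.14 over 10 members. BCL2, itself an oestrogen-responsive survival gene, was 10.1-fold lower and the chaperone partner BAG3 2.65-fold lower. BIRC2 was 2.34-fold higher, and BAG1 differed by -0.76. Of 14 pro-apoptotic genes, 4 were at least 2-fold higher and 0 at least 2-fold lower (median 0.23, random range -0.46 to 0.37). DAPK1 was at least 7.21-fold higher, PMAIP1 3.54-fold, the apoptosome gene APAF1 2.61-fold and BOK 2.28-fold. Targets of p53 went both ways (3 of 16 at least 2-fold higher, 4 lower, median 0.01). GDF15, a stress-induced cytokine, was 10.4-fold lower and TP53INP1 3.20-fold lower, while PLK2 was 3.71-fold and SESN2 2.92-fold higher.

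Break repair genes had 4 of 21 members at least 2-fold lower and 0 at least 2-fold higher (median -0.30, inside the random range). These were RAD51C (3.33-fold), BRIP1 (2.91-fold), NBN (2.28-fold) and BARD1 (2.03-fold). In excision and mismatch repair, the glycosylase gene NEIL3 was at least 11.3-fold lower and PMS2 2.13-fold lower among 12 members (median -0.24). MSH3 differed by -0.88 and NEIL1 by -0.77. PMS2 has near-identical pseudogene copies.

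Cell cycle and mitosis genes were close to balanced, with 31 of 37 within 2-fold and a median of -0.08. The proliferation marker MKI67 was 2.67-fold lower and GINS2 2.83-fold lower, while the spindle checkpoint kinase gene TTK was 3.34-fold and CCNE1 2.20-fold higher. Among G1 regulators (median -0.10 over 10), the inhibitor gene CDKN2A was 6.93-fold higher (a lower limit if MCF7 lacks the gene) and the kinase gene CDK6 5.22-fold higher. The retinoblastoma gene RB1 was 4.63-fold lower, at 7.84 against 5.63, and RBL2 differed by -0.22.

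Cholesterol synthesis genes had a median of -0.41 at percentile 2.79, at the edge of the random range, with 3 of 15 at least 2-fold lower and 1 higher. INSIG1 (2.93-fold), DHCR7 (2.91-fold) and HMGCS1 (2.06-fold) were lower and the sterol carrier gene STARD4 was 2.12-fold higher. In glycolysis and hypoxia (median 0.19 over 15), the lactate dehydrogenase gene LDHB was below the floor in MCF7 and at least 16.4-fold higher. ADM was 3.71-fold and NDRG1 2.84-fold higher, and the hexokinase gene HK2 2.17-fold lower. Oxidative phosphorylation genes (median 0.13 over 12) included COX6C, 4.30-fold lower. COX7A2 differed by 0.77, UQCRC1 by 0.70 and UQCRH by 0.62. In the unfolded protein response (median 0.18 over 14), DDIT3 was 4.99-fold and SDF2L1 2.11-fold higher, and XBP1 2.66-fold and ASNS 2.05-fold lower. Heat shock genes (median -0.16 over 9) included HSPB8, at least 2.57-fold lower, and HSF1, 2.23-fold higher. HSPB1, among the brightest genes, differed by -0.21.

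Ribosomal protein genes, a list chosen as not expected to differ, were all within 2-fold over 31 members, with a median of -0.04. Their largest differences were those of RPL28 (-0.76), RPS6 (0.72), RPL24 (-0.62) and RPS23 (-0.55). The proteasome list had no member named by the annotation used here.

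Interferon-stimulated genes were higher in MCF7_ADR. Of 28 compared members, 14 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 0.99 (random range -0.28 to 0.22). HERC5, an ISG15 ligase, was at least 6.28-fold higher. OASL was 6.07-fold, the RNA sensor gene RIGI 5.69-fold and MX2 4.59-fold higher. With a floor at the 70th percentile the median was 0.65. Cytokine and chemokine genes went both ways, with 6 of 17 at least 2-fold higher and 5 lower (median 0.11). IL18 was at least 27.5-fold higher, the adhesion gene ICAM1 8.20-fold and CCL5 7.80-fold, while the calgranulin gene S100A8 was at least 8.60-fold lower. Of the antigen presentation list only B2M (-0.76) and TAPBP (-0.26) were compared.

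**Figure D3:**
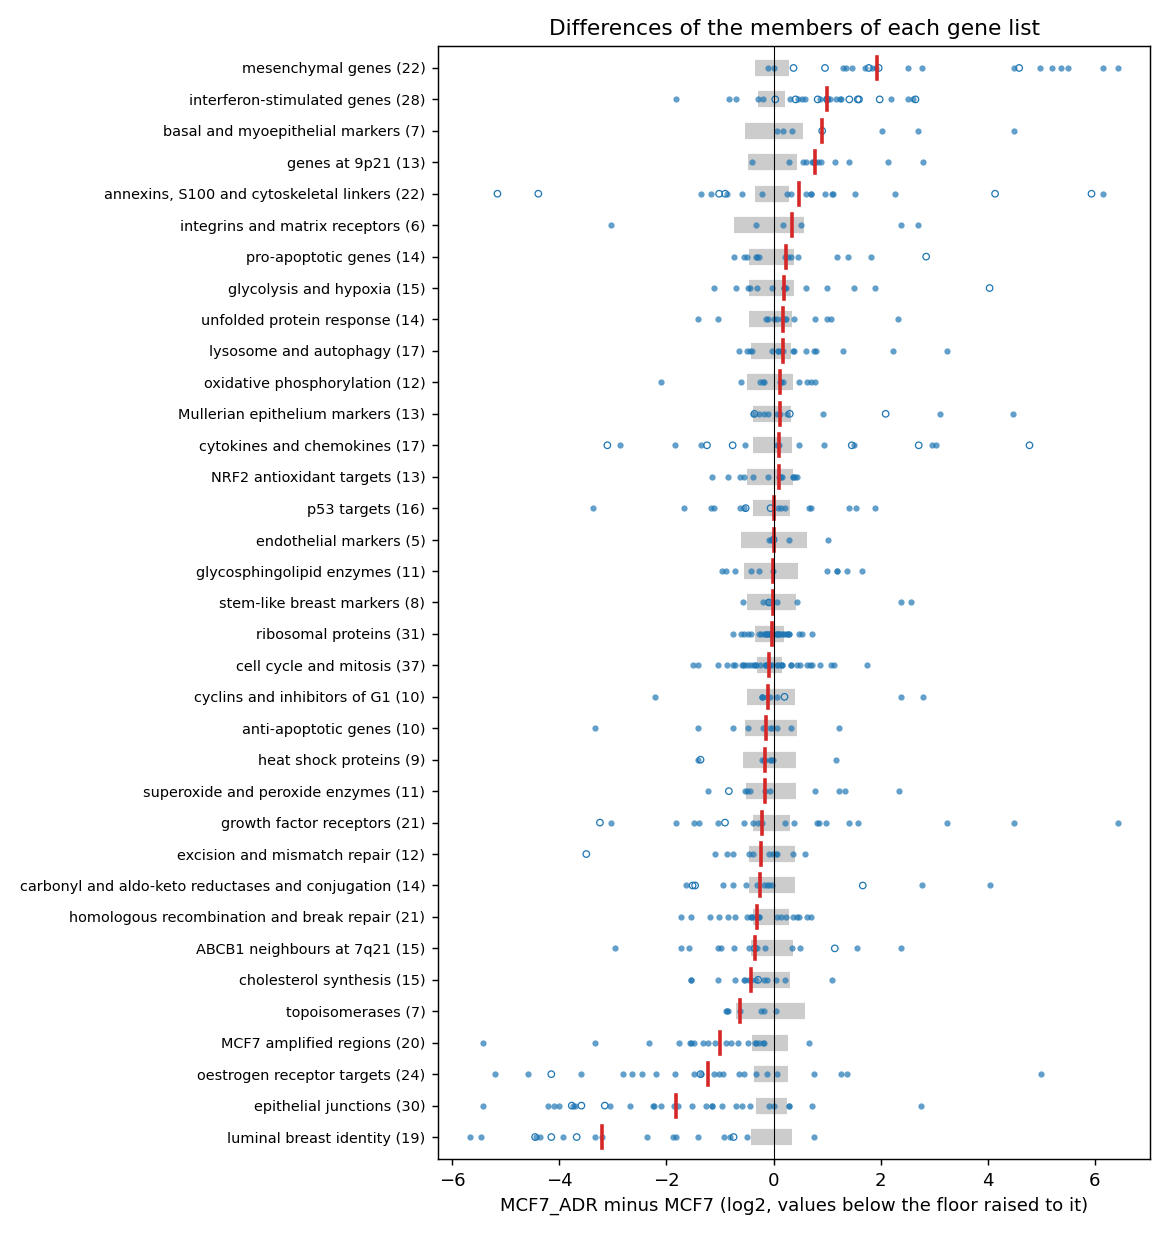
Difference between MCF7_ADR and MCF7 (x axis, log2) for each compared member of the 35 gene lists that could be placed, with the number of members after each name; filled points are measured above the floor on both arrays and open points are limits. Red bars are list medians and grey bars the central 95% of medians of matched random lists; 4 lists lie below their grey bar and 5 above it.

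Genes of regions known to be amplified in MCF7 (parts of 17q23 and 20q13) had a median of -0.99 (random range -0.40 to 0.26). Of 20 members, 10 were at least 2-fold lower and 0 at least 2-fold higher. SULF2, PARD6B (10.1-fold), the T-box gene TBX2 (4.99-fold) and BCAS1 (3.41-fold) were the lowest. Genes at 9p21 had a median of 0.77 (random range -0.48 to 0.44), with 4 of 13 at least 2-fold higher and 0 lower. These were CDKN2A (5.42 in MCF7 and 8.22 in MCF7_ADR), the neighbouring methylthioadenosine phosphorylase gene MTAP (6.35 and 8.48, 4.40-fold), PLIN2 (2.65-fold) and DMRTA1 (2.22-fold). Part of this region is known to be lost in MCF7, and if so the MCF7 values of CDKN2A and MTAP are background and their folds lower limits. In that case background can lie above the floor. The folds of other genes with MCF7 values as low, such as EGFR (5.81) and VIM (6.14), may then be lower limits too. Neighbours of ABCB1 at 7q21 had a median of -0.35, inside the random range, with 3 of 15 at least 2-fold higher and 4 lower. Among them ELAPOR2 was 7.76-fold, GATAD1 3.33-fold and ANKIB1 2.97-fold lower. CDK6, RUNDC3B (2.95-fold) and CDK14 (at least 2.21-fold) were higher.

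Among Mullerian epithelium markers (median 0.11 over 13, inside the random range), 3 were at least 2-fold higher and 0 lower. These were the surface protein gene MSLN (22.1-fold), the lineage factor PAX8 (8.66-fold, at 5.93 in MCF7 and 9.05 in MCF7_ADR) and WT1 (at least 4.27-fold). FOLR1 differed by 0.92. With a floor at the 70th percentile, which left 7 members, the median was 0.83. Of 4 fibroblast markers compared, LUM was at least 3.42-fold and PDPN 2.15-fold higher, while FBLN1 differed by 0.75 and THY1 by -0.10. Of 3 haematopoietic markers compared, LCP1, also known in epithelial cancer cells, was 11.3-fold lower, TYROBP differed by -0.64 and LAPTM5 by -0.01. Endothelial markers had a median of 0.00 over 5, with ESAM 2.03-fold higher, ERG at 0.28, VWF at -0.09 and CLDN5 at -0.06.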

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

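All tests under this heading were chosen after the differences had been seen.

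Signal outside the named genes was singled out because the comparisons do not use it. Among 15661 probe sets without a gene name that passed the floor on an array, 346 were at least 4-fold higher in MCF7_ADR than in MCF7 and 235 at least 4-fold lower. The highest were probe sets 16798202 and 16798198, with identical values on both arrays and at least 340.02-fold higher in MCF7_ADR. The lowest were 16820486 (at least 116.0-fold lower) and 17096030 (at least 74.99-fold lower). Their genes are not named here.

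For the opposite shift of luminal and mesenchymal genes, an array-wide loss of signal would move genes of the same level alike. The mesenchymal list lay at percentile 100 of random lists matched on level, and the luminal list at percentile 0 of its own. These percentiles are the pattern itself rather than a separate test, and argue only against a shift shared by genes of the same level. A minority of foreign cells in an otherwise MCF7 culture is argued against by the luminal median of -3.21 (bootstrap SD 0.81), since a culture whose RNA came mostly from MCF7 would not go below -1. The median was -2.37 with the mean of a gene's probe sets and over members above the floor on both arrays, and -2.49 with a floor at the 70th percentile. These values also lie below -1, but by a margin small enough against that SD that the question is not settled under those settings. A candidate explanation that stays open is that the MCF7_ADR cells do not descend from MCF7: MTAP and CDKN2A lie in a segment known to be lost in MCF7, and the smaller of their differences was 2.14. Lines circulated under similar names are known to have been reassigned to an ovarian carcinoma origin, but the Mullerian marker list lay at percentile 81.8, and at 99.7 over the 7 members left by a floor at the 70th percentile, which leaves that origin undecided even though PAX8, MSLN and WT1 were higher. A shift of MCF7 cells towards a mesenchymal state under doxorubicin was not tested and stays open too. It would not by itself explain higher MTAP and CDKN2A if MCF7 lost both copies of that segment. Whether the MCF7 culture used here lost them was not measured.

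The interferon-stimulated genes were higher as a list, and several are dim in MCF7. Dim values near the floor are argued against, since members above the floor on both arrays alone put the list at percentile 100 of matched random lists. For blood cells in the MCF7_ADR culture, 0 of 3 compared haematopoietic markers were at least 2-fold higher. LYZ, SRGN, CD14 and CD53 were below the floor on both arrays. These values argue only against a large share of blood cells. A small share is not excluded, since few markers were compared and LCP1 was already at 9.28 in MCF7. A drug effect and a difference of lineage both stay open and were not tested.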

How the results depend on the processing

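No replicate could be left out, since each line has 1 array, and no result carries a p-value. The median shift and quantile normalization kept every count within 1.5 times and every list median within its bootstrap SD over members. They moved little because the deposited arrays were already close to equal. Probe set names of this array carry no suffix for shared sequence, so that alternative was not run, and the pseudocounts did not apply to a log2 table. With a floor at the 70th percentile, the number of genes at least 4-fold higher was 192 against 305. The same floor gave medians of 0.65 for interferon-stimulated genes, 0.38 for lysosome and autophagy genes and 0.83 for Mullerian markers. The luminal median was -2.37 with the mean of a gene's probe sets, and also -2.37 over members above the floor on both arrays, a setting chosen after seeing the data. The cause of these moves was not tested. No named gene with a difference of at least 2-fold changed direction. Such a change was unlikely from the start, since floors mostly alter size and named genes were chosen for probe sets that agree. Of 978 values of 164 named genes under 6 alternatives, 890 lay within 0.49 of the first value and 88 moved by more. Of those 88, 53 came with the floor at the 70th percentile. Among them were 7 of the 10 highest and 6 of the 10 lowest genes above the first floor on both arrays, all with smaller folds, such as AXL (at least 56.7-fold), SNAI2 (at least 17.8-fold), HEG1 (at least 14.3-fold) and GRHL2 (at least 19.7-fold). The basal list lay inside its random range with a floor at the 30th percentile (percentile 95.1) and with no floor (94.95). Cholesterol synthesis entered the low tail with those settings (percentiles 1.98 and 2.34), and the Mullerian list the high tail with a floor at the 70th percentile (99.7). Fibroblast markers, too few to place before, lay in the high tail with no floor (median 0.75 over 5 members, percentile 98.3). Genes dim on 1 array have only a limit on their fold, and the 3562 named genes below the floor on both arrays were not compared.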

Other observations

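Neighbouring genes differed together along the chromosomes. In windows of 21 consecutive compared genes, the strongest stretch lower in MCF7_ADR ran from MLKL to CENPN and includes WWOX, MAF and BCAR1, with a median of -1.70 and 15 of 21 genes at least 2-fold lower. The next ran from ARMC10 to DLD, with RELN, NAMPT and SRPK2 (median -1.40, 15 of 21 at least 2-fold lower), and from TRRAP to LAMTOR4, with MCM7 and COPS6 (median -1.12). The stretch with MCM7 also holds MIR25, MIR93 and MIR106B, counted as separate genes. Overlapping transcripts were not merged. Lower too was the stretch from FZD1 to LMTK2 (median -1.03). It holds AKAP9, ANKIB1 and GATAD1 of the 7q21 list, and also CDK6, which was higher. The strongest stretch higher in MCF7_ADR ran from SH3BGRL2 to RRAGD, with TTK and TPBG, at a median of 1.23 with 15 of 21 genes at least 2-fold higher. Another ran from IFI44 to ZNF644, with BCL10 and DDAH1 (median 0.98, 10 of 21 at least 2-fold higher). Of 10848 overlapping windows, 171 lay above 0.76 and 177 below -0.77, limits that the most extreme window of 200 shuffled gene orders passed in 5% of them in each direction.

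Copy number differences between the lines are a candidate explanation, and both tests below were fixed before their results were seen. Differences of genes 5 places apart correlated at 0.119, against -0.0188 to 0.0161 in 1000 shuffles, and at 0.0705 for genes 20 places apart (across genes, with differences limited to 2 log2 units either way). Probe sets shared between adjacent duplicated genes are argued against as the whole cause, since the correlation 5 places apart was 0.616 of that 1 place apart (0.194). Shared regulation of neighbouring genes was not tested and stays open, and no copy number was measured.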
